A study of Oryza sativa with 3 samples.

How the data were processed

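Total RNA from roots of rice seedlings treated with juglone or water was amplified and labelled with Cy5 (juglone) or Cy3 (water) and hybridised together on 3 Agilent 2-colour rice arrays, per the labels' protocols, with no dye swap. Per the file headers, the authors quantified the scans with Agilent Feature Extraction, version 9.5.3.1 on scanner G2505B for replicates 1 and 2 and version 10.5.1.1 on scanner G2505C for replicate 3. Replicates 1 and 2 shared a slide, and replicate 3 was on another. The deposited scanner files give each spot's mean intensity and local background intensity in both channels, not background corrected, and a processed signal that Feature Extraction had background subtracted and dye normalised, per the file headers. They also give the log10 ratio of red over green processed signal, per the file headers. The deposited value table of the series holds log2 ratios whose scale is not given in the labels. Set against each array's scanner values they were log2 of red over green processed signal, in the same direction and with no further centring. In the headers, observed against stated log ratios of spike-in RNAs had slopes of 0.829, 0.820 and 0.831, all below 1, so the spike-in ratios were compressed. Of the non-control spots, 83.3%, 86.0% and 88.8% were well above background in the juglone channel of replicates 1 to 3 and 80.0%, 83.5% and 89.2% in the water channel. The number of arrays limits the precision.

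Analysis started from the mean and background intensities in R 4.3.3 with limma 3.58.1 and the data.table package in version 1.17.8. Background was corrected with normexp at an offset of 50 on all 45151 spots, and ratios were normalised within arrays by loess with control spots at weight 0. The 1417 scanner control spots, 590 control spots of the array design and 74 spot values marked as outliers were left out. Spots of a probe were averaged, and a probe was kept if at least 1 channel was well above background on at least 2 arrays. A gene was represented by its probe of highest mean log2 intensity, which mattered for the 7001 genes with several probes, and this left 25645 loci and 285 microRNA probes. The log2 ratio of juglone over water was tested against 0 with limma's lmFit and eBayes (two-sided, total degrees of freedom 5.28), and genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen, fallen or changed. Juglone and water RNA were paired by sharing an array, so effects common to both channels of an array cancel in the ratio. The ratios still differed in spread between arrays, with interquartile ranges of 0.599, 0.653 and 0.409 on the log2 scale for replicates 1 to 3. Values are mean log2 ratios ± SD over the 3 arrays. For genes not well above background in a channel on every array the fold is a bound, taken per channel after loess and Aquantile and open to dye bias. None of the genes named is of that kind, and 11 tested genes had a saturated spot.

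Gene lists (38) were fixed before the data were examined as patterns on the descriptions in the scanner files and tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each with Benjamini-Hochberg adjustment over the lists. Named genes follow a rule fixed at the same time. It takes the 6 largest rises and 6 largest falls past the threshold with the same direction on all arrays and an informative description, and in each list the largest rise and largest fall among passing members. It gave 82 genes, and values are printed for those of the called lists and for part of those of the others, chosen after their values were seen. Gene names are those of the array's design and can be old. Of 29695 loci on the array 0 matched the reference gene table by locus identifier, and 0 accessions matched, so coordinates were not used here, and the order of loci along a chromosome was taken from their locus numbers. The genome build is not given in the sources used here.

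The test was checked on simulated ratios for 25930 genes, with 200 genes changed in each of 20 simulations of the juglone comparison. With variances drawn from the prior fitted to the arrays, 0.70% of changes of 0.5 on the log2 scale, 66.6% of changes of 1, 96.9% of changes of 2 and 99.7% of changes of 4 were recovered, and 5.11% ± 1.86 (SD) of the calls were false. A first version drew from the shrunken variances of the real genes, recovered 27.6%, 98.3%, 99.9% and 100% of changes of these sizes, gave 11.4% ± 2.75 false calls and was replaced as the main check after its results were seen. It shows that the share of false calls can pass the nominal level where the variance model is off. Each simulation changed 200 genes, while 9045 were called in the data, so the adjusted threshold was stricter in the simulations. The recovered shares therefore do not carry over to the data. In simulated lists with independent genes, every member of 2 lists was shifted by 0.5 on the log2 scale and no other gene was changed. Of these, 40 of 40 shifted lists were called, and 1 of 720 unshifted lists. Most lists in the data had smaller medians and both rises and falls, and many genes outside them changed, so these shares do not carry over either. Alternatives numbered 21, of which 17 were fixed before the data were examined and 4 were added after. They cover background correction, normalisation, filters, probes per gene, saturation, variance model, array weights, pairing, slide, centre and leaving out each replicate. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.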

Results

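Roots of rice seedlings (cultivar TN-67, 6 days old) that had been exposed to juglone were compared with roots exposed to water. Juglone is a naphthoquinone released by walnut trees that inhibits the growth of other plants, and the question was how rice roots respond to it. Each of 3 arrays, labelled as biological replicates, held the RNA of juglone-treated roots in the Cy5 channel and the RNA of water-treated roots in the Cy3 channel. The labels disagree on the dose, which is 10 mM in the treatment field and 10 μM in the description, so no statement on dose is made, and the exposure time is not given in the sources used here. On the 3 arrays, 83.3%, 86.0% and 88.8% of the non-control spots were well above background in the juglone channel, and 80.0%, 83.5% and 89.2% in the water channel. All p-values rest on these 3 arrays, and their number limits the precision of every value. Across genes, which are not replicates, the log2 ratios correlated with a Pearson r of 0.916 between replicates 1 and 2, which shared a slide, scanner and software version. It was 0.872 between replicates 1 and 3 and 0.831 between replicates 2 and 3.

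Heat shock protein genes held 4 of the 6 largest rises among genes with an informative description. A class II small heat shock protein gene (Os01g0184100) on chromosome 1 rose 114-fold in juglone-treated roots, with a log2 ratio of juglone over water of 6.84 ± 0.52 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 6.48e-05). Its juglone signal was saturated on 2 of the arrays, so its fold, SD and rank are uncertain, and on the other array, replicate 3, its log2 ratio was 6.24. Heat shock protein 81-1 (Os04g0107900, chromosome 4), of the HSP90 family of chaperones, rose by 6.07 ± 0.28 on the log2 scale, heat shock protein 26 (Os03g0245800, chromosome 3) by 6.01 ± 0.15 and the low molecular mass heat shock protein Oshsp17.3 (Os03g0266900, chromosome 3) by 5.84 ± 0.11. An ethylene-responsive transcriptional coactivator (Os06g0592500, chromosome 6) rose by 6.05 ± 0.65 and a protein with an IQ calmodulin-binding region (Os11g0506800, chromosome 11) by 5.85 ± 0.51. Small heat shock protein genes resemble each other in sequence, so signal shared between close relatives is possible on such probes and their single values are uncertain to that extent.

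Falls were smaller. A protein kinase domain gene (Os01g0935800, chromosome 1) had the largest fall, with a log2 ratio of -2.20 ± 0.51 (SD, n = 3; limma, Benjamini-Hochberg adjusted p = 0.00162). A glyoxal oxidase domain gene (Os03g0258900, chromosome 3) had a log2 ratio of -1.99 ± 0.25, a GASA5-like gene (Os09g0414900, chromosome 9) of -1.95 ± 0.57, a haem peroxidase (Os07g0104500, chromosome 7) of -1.93 ± 0.50 and a calcium-binding protein (Os02g0606500, chromosome 2) of -1.74 ± 0.31. With the channels taken as unpaired samples the call of Os07g0104500 ended. The cyclin gene Os07g0556000 on chromosome 7, of the family that drives the cell cycle, had a log2 ratio of -1.69 ± 0.05.

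**Figure D1:**
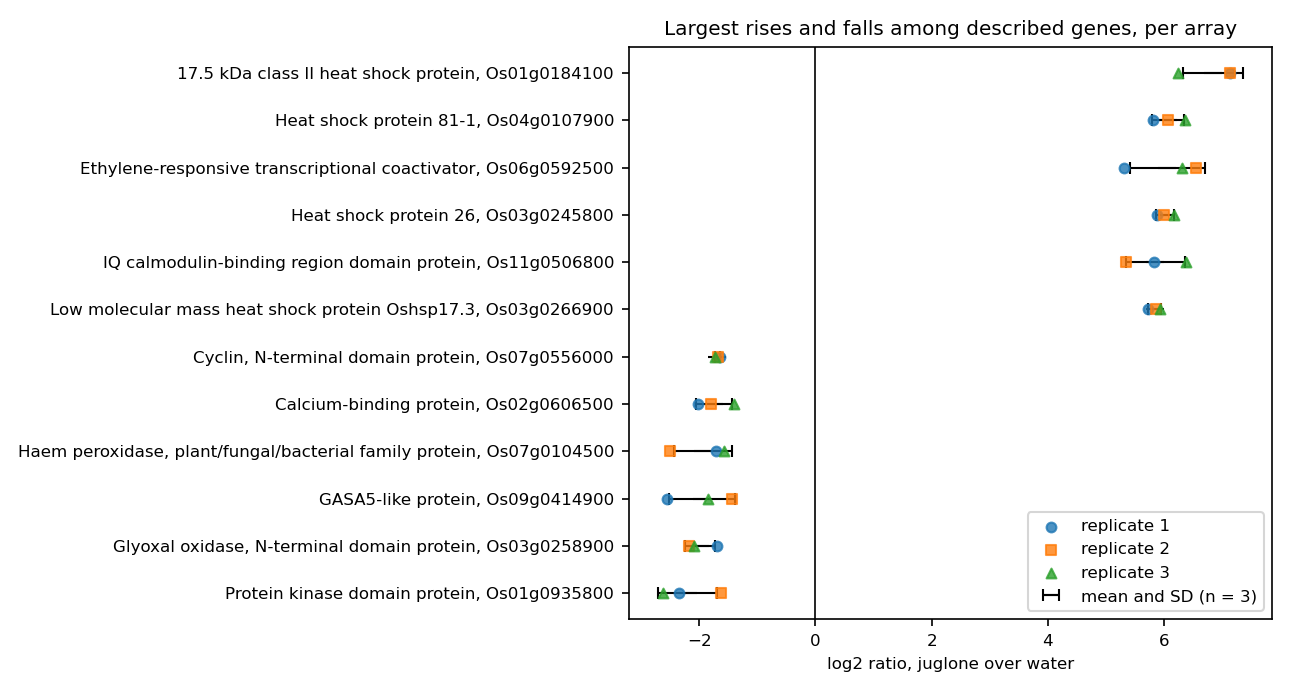
Log2 ratio of juglone over water (horizontal axis) for the 6 largest rises and 6 largest falls among genes with an informative description; symbols are the 3 arrays and bars the mean and SD (n = 3). The mean ratios run from -2.20 to 6.84, and each gene lies on the same side of 0 on all 3 arrays.

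Of 25930 genes and microRNA probes tested, 9045 (34.9%) changed, of which 5444 rose and 3601 fell (limma on the 3 log2 ratios, Benjamini-Hochberg). At least 2-fold changes were mostly rises, with 2089 rises and 294 falls. They were 2294 and 1066 with the scanner software's log ratio, 2635 and 606 with that ratio moved to the main medians, 2331 and 191 with median centring alone, 2516 and 149 with ribosomal centring, 1782 and 187 with unpaired channels and 2365 and 524 without replicate 3. Ribosomal centring and the move to the main medians were chosen after seeing the data. At least 4-fold changes comprised 744 rises and 1 fall, the protein kinase gene above, and at least 8-fold changes 318 rises and 0 falls, all past the adjusted threshold. Without adjustment, 12331 genes had a limma p under 0.05. Of the 9045 changed genes, 9044 had a value and the same direction on every array, and the other lacked a value on 1 array. Passing the threshold with 3 arrays nearly requires this, so it adds no separate support. In 183 of the rises the water signal was not well above background on any array, and in 4 of the falls the juglone signal was not, so their fold changes are bounds only. Every array had the same dye orientation, so a difference between the dyes at a gene cannot be separated from juglone. The split between rises and falls depended on the centre of the ratios. With the scanner software's own log ratio the median of all genes was shifted by -0.15 on the log2 scale, and 3975 genes rose (40.1% of the changed, against 60.2%) and 5939 fell. Relative to that shift, with each array's median put back, 5013 rose and 3359 fell (59.9% rises). The deposited value table, which carries the same ratios, gave 3978 rises and 5943 falls (40.1%), and centring on the ribosomal protein genes gave 7119 and 2040 (77.7%). Without replicate 1, 3139 genes changed, and without replicate 2, 4449. Within the slide that held replicates 1 and 2, 10595 genes changed, and with slide as a term in the fit, also added after seeing the data, 9709 changed. The other slide held a single array, read with another scanner and software version, and allows no test, so slide cannot be told apart from these. As unpaired channels, 3866 genes changed.

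**Figure D2:**
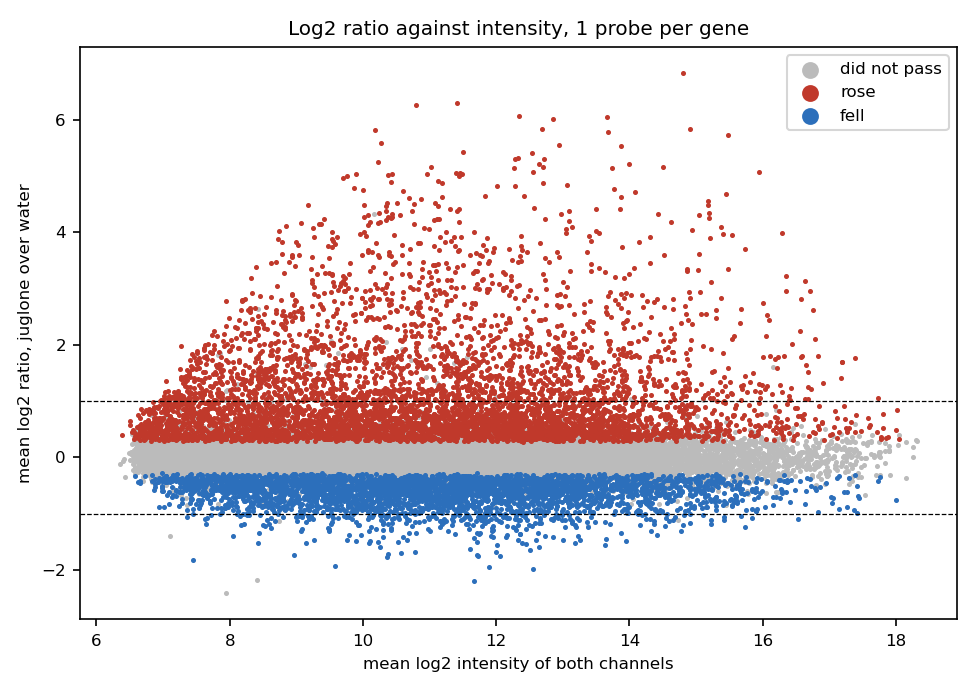
Mean log2 ratio of juglone over water (vertical axis) against the mean log2 intensity of both channels (horizontal axis) for 25930 genes and microRNA probes, with dashed lines at 2-fold. Points past the threshold number 5444 above 0 and 3601 below, and the share above 0 falls from 60.2% to 40.1% with the scanner software's log ratio.

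The lists of heat shock proteins and of heat stress transcription factors were called up. Of 149 tested heat shock proteins and chaperones, 57 rose, 12 fell and 80 did not pass, and adjusted over the list alone 61 rose and 17 fell. The median log2 ratio of that list was 0.15 and its mean 1.00, with 36 members rising at least 2-fold (limma camera, Benjamini-Hochberg adjusted p = 0.000668, against an adjusted p = 0.529 with an estimated correlation). The median became 0.03 with the scanner software's log ratio (46 rises and 22 falls) and 0.31 with median centring alone. The largest fall in the list was that of a DnaJ family gene (Os05g0427900), with a log2 ratio of -0.94 ± 0.26, a call that ended with unpaired channels. Of 22 heat stress transcription factors, a family that includes activators of heat shock genes, 13 rose, 0 fell and 9 did not pass, and 14 rose and 0 fell adjusted over the list alone. Their median was 0.66 (limma camera, Benjamini-Hochberg adjusted p = 1.13e-05, against an adjusted p = 0.529 with an estimated correlation), and the largest rise was Os03g0745000 with 3.68 ± 0.26.

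Lists of detoxification and conjugation were called up as well. Of 65 glutathione S-transferases, which join glutathione to electrophilic compounds, 37 rose, 3 fell and 25 did not pass, and adjusted over the list alone 39 rose and 4 fell. The median was 0.63 (limma camera, Benjamini-Hochberg adjusted p = 1.08e-07, against an adjusted p = 0.529 with an estimated correlation). Glutathione S-transferase GST 20 (Os10g0530600) rose by 4.41 ± 0.34, and another member (Os10g0530200) had a log2 ratio of -0.88 ± 0.28. Of 119 UDP-glycosyltransferases, which attach sugars to small molecules, 46 rose and 19 fell, and 51 and 24 adjusted over the list alone. Their median was 0.19 (limma camera, Benjamini-Hochberg adjusted p = 0.0466, against an adjusted p = 0.579 with an estimated correlation). Os02g0755900 rose by 5.53 ± 0.33, and Os06g0271000 had a log2 ratio of -1.19 ± 0.73. Of 190 cytochrome P450 genes 65 rose and 23 fell, and 70 and 28 adjusted over the list alone. Their median was 0.18 (limma camera, Benjamini-Hochberg adjusted p = 0.0429, against an adjusted p = 0.529 with an estimated correlation). CYP72A5 (Os01g0627800) rose by 4.51 ± 1.43, and Os08g0547900 had a log2 ratio of -0.99 ± 0.26. Of 73 ABC transporters 22 rose and 5 fell, and 23 and 6 adjusted over the list alone. Their median was 0.12 (limma camera, Benjamini-Hochberg adjusted p = 0.0438, against an adjusted p = 0.529 with an estimated correlation), and became -0.02 with the scanner software's log ratio. The PDR-like transporter PDR3 (Os01g0609300) rose by 3.24 ± 0.36, and Os08g0167000 had a log2 ratio of -0.60 ± 0.38. The calls of the UDP-glycosyltransferase, P450 and ABC transporter lists each ended with median centring alone, with ratios scaled between arrays and with no filter on dim probes. That of the UDP-glycosyltransferases also ended without replicate 2 (median 0.13), with slide as a term (median 0.15), with ribosomal centring, with probes well above background on all 3 arrays and with genes brighter than every random-sequence probe. That of the ABC transporters also ended without replicate 3 (median 0.12), with each probe on its own, with the scanner software's log ratio, as given or moved to the main medians, and with the deposited value table. Without replicate 1 or 2 the calls of Os06g0271000 (-1.03 and -0.94) and Os08g0167000 (-0.51 and -0.47) ended, the latter also with median centring alone.

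Of 38 antioxidant enzymes 15 rose and 1 fell, and 17 and 1 adjusted over the list alone. Their median was 0.25 (limma camera, Benjamini-Hochberg adjusted p = 0.0110, against an adjusted p = 0.529 with an estimated correlation). Their largest rise was peroxiredoxin 6 (Os07g0638300), a thiol peroxidase, with 3.41 ± 1.49, and the fall was an iron superoxide dismutase (Os06g0115400) with -0.36 ± 0.10. The call of Os07g0638300 ended without replicate 1 (3.06), and that of Os06g0115400 without any of replicates 1, 2 or 3 (-0.38, -0.40 and -0.31), with median centring alone, with ratios scaled between arrays, with ribosomal centring and with the scanner software's log ratio moved to the main medians. Class III peroxidases, secreted haem enzymes that act in the cell wall, went the other way, with 15 rises and 43 falls among 114 members, and 19 and 44 adjusted over the list alone. Their median was -0.16 (limma camera, Benjamini-Hochberg adjusted p = 0.00398, against an adjusted p = 0.529 with an estimated correlation). Os11g0112400 of this list rose by 3.09 ± 1.02, and the haem peroxidase Os07g0104500 named above had the list's largest fall.

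The WRKY, NAC and AP2/ERF lists of transcription factors, families with known parts in stress responses, were called up, and the MYB list was not. Of 65 WRKY genes 36 rose and 5 fell, and 38 and 6 adjusted over the list alone. Their median was 0.63 (limma camera, Benjamini-Hochberg adjusted p = 1.13e-05, against an adjusted p = 0.529 with an estimated correlation). WRKY transcription factor 28 (Os06g0649000) rose by 4.87 ± 0.88, and Os05g0129800 had a log2 ratio of -1.18 ± 0.77. Of 61 NAC genes 27 rose and 9 fell, and 30 and 9 adjusted over the list alone. Their median was 0.30 (limma camera, Benjamini-Hochberg adjusted p = 0.0157, against an adjusted p = 0.529 with an estimated correlation). The gene described as ANAC002 (Os01g0816100) rose by 4.52 ± 0.22, and Os05g0563000 had a log2 ratio of -0.75 ± 0.22. Of 87 AP2/ERF genes 31 rose and 12 fell, and 35 and 14 adjusted over the list alone. Their median was 0.30 (limma camera, Benjamini-Hochberg adjusted p = 0.0404, against an adjusted p = 0.579 with an estimated correlation). Os02g0546600 rose by 5.26 ± 0.08, and Os10g0560700 had a log2 ratio of -0.95 ± 0.43. The NAC call ended with median centring alone and the AP2/ERF call with ratios scaled between arrays, with each probe on its own and with genes brighter than every random-sequence probe. The call of Os05g0129800 ended without replicate 1 (-0.83) or 2 (-1.12), and that of Os10g0560700 with unpaired channels.

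Among defence and hormone genes, 40 of 99 pathogenesis-related proteins rose and 9 fell, and 44 and 10 adjusted over the list alone. The median was 0.43 (limma camera, Benjamini-Hochberg adjusted p = 0.00572, against an adjusted p = 0.579 with an estimated correlation). A class III chitinase homologue (Os11g0702100) rose by 3.66 ± 0.78, and a PR-1a gene (Os02g0786900) had a log2 ratio of -1.36 ± 0.39. Of 36 genes of jasmonate synthesis and response 15 rose and 2 fell, and 15 and 3 adjusted over the list alone. Their median was 0.36 (limma camera, Benjamini-Hochberg adjusted p = 0.0429, against an adjusted p = 0.579 with an estimated correlation). A ZIM domain gene (Os10g0392400), of the family that holds repressors of jasmonate signalling, rose by 3.31 ± 0.47, while allene oxide synthase (Os02g0218800), an enzyme of jasmonate synthesis, had a log2 ratio of -0.97 ± 0.30. Of 17 gibberellin genes 8 rose and 1 fell, and 8 and 1 adjusted over the list alone. Their median was 0.25 (limma camera, Benjamini-Hochberg adjusted p = 0.0404, against an adjusted p = 0.529 with an estimated correlation). The largest rise there was a gibberellin 2-beta-dioxygenase (Os01g0757200), an enzyme that inactivates gibberellin, with 3.78 ± 0.50, and the fall was OsGAI (Os03g0707600) with -0.60 ± 0.09. The jasmonate call ended without replicate 1 (median 0.26), with unpaired channels, with slide as a term, with median centring alone, with ratios scaled between arrays, with ribosomal centring and with genes brighter than every random-sequence probe, and the gibberellin call with ratios scaled between arrays. The call of OsGAI ended without replicate 1 (-0.63).

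The lists of the cell cycle and the cell wall were called down. Of 109 genes of the cell cycle and DNA replication 2 rose, 32 fell and 75 did not pass, and adjusted over the list alone 2 rose and 28 fell. The median was -0.21 (limma camera, Benjamini-Hochberg adjusted p = 1.25e-05, against an adjusted p = 0.529 with an estimated correlation). Besides the cyclin Os07g0556000, the list held the cyclin Os02g0438200, which rose by 0.41 ± 0.12. Of 146 genes of cell wall expansion and synthesis 12 rose and 49 fell, and 12 and 51 adjusted over the list alone. Their median was -0.20 (limma camera, Benjamini-Hochberg adjusted p = 0.000285, against an adjusted p = 0.529 with an estimated correlation). A fasciclin domain gene (Os08g0502400), a cell adhesion type rather than a wall-building enzyme, had a log2 ratio of -1.53 ± 0.26, and a pectin methylesterase (Os01g0311800) rose by 1.58 ± 0.16. Of 48 core and linker histones 5 rose and 12 fell, also when adjusted over the list alone. Their median was -0.14 (limma camera, Benjamini-Hochberg adjusted p = 0.0429, against an adjusted p = 0.676 with an estimated correlation), and became 0.11 with median centring alone. Histone H3 (Os11g0155900) had a log2 ratio of -0.99 ± 0.12 and Histone H2B.2 (Os05g0460500) rose by 2.07 ± 0.28. The histone call ended without replicate 3 (median -0.05), with median centring alone, with the scanner software's log ratio, as given or moved to the main medians, with the deposited value table, with ratios scaled between arrays, with each probe on its own and with genes brighter than every random-sequence probe. Of 300 ribosomal protein genes 10 rose and 53 fell, but 1 and 0 adjusted over the list alone. Their median was -0.14 (limma camera, Benjamini-Hochberg adjusted p = 4.00e-05, against an adjusted p = 0.637 with an estimated correlation), and became 0.08 with median centring alone, where the call ended. The ribosomal median was -0.25, -0.10 and -0.06 on the 3 arrays. 60S ribosomal protein L10 (Os05g0169100) rose by 1.41 ± 0.15, and 40S ribosomal protein S13 (Os07g0572900) had a log2 ratio of -0.95 ± 0.41. Without replicate 1 or 2 the calls of Os02g0438200 (0.40 and 0.36) and Os07g0572900 (-0.85 and -0.82) ended, the former also with the scanner software's log ratio and the deposited value table.

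**Figure D3:**
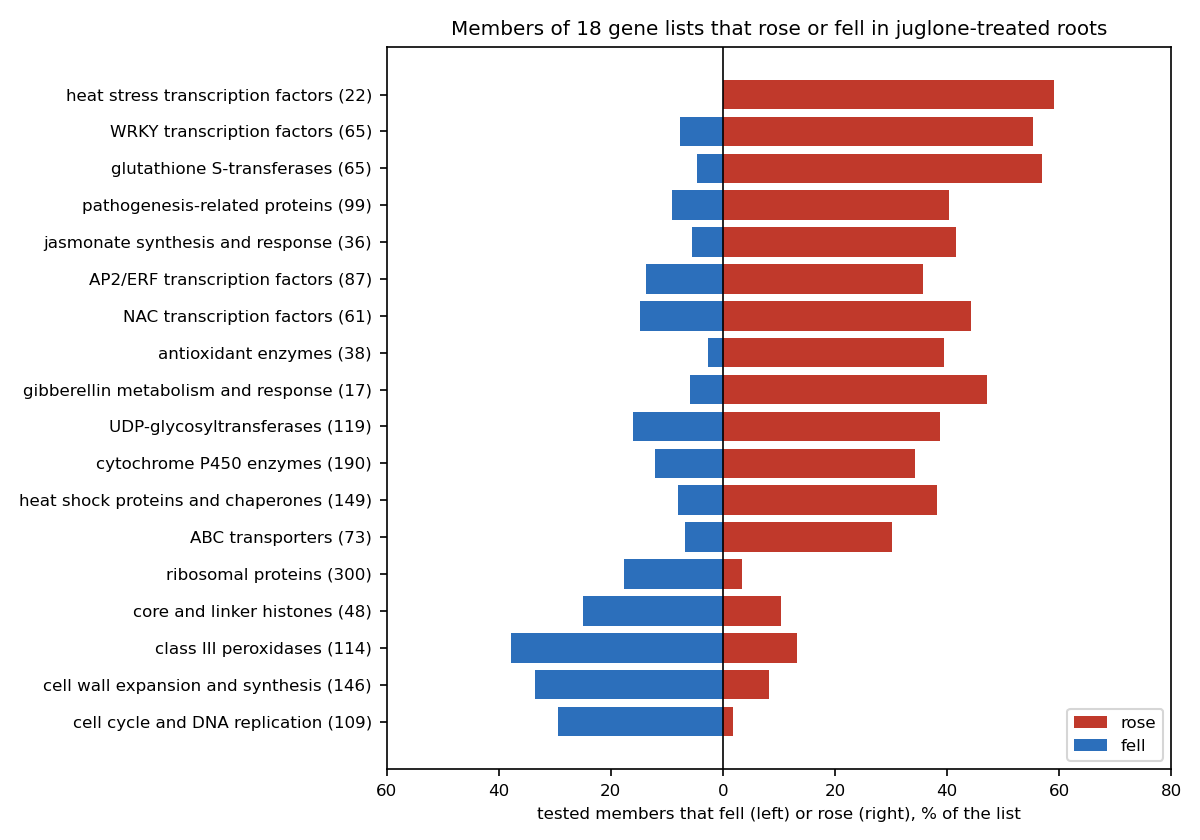
Percent of the tested members of 18 gene lists that rose (right) or fell (left) past the threshold, with the number tested in parentheses and the lists ordered by median log2 ratio. The 13 lists called up lie above the 5 called down; the median of the ribosomal and histone lists turned positive with median centring alone, and that of the ABC transporters negative with the scanner software's log ratio.

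In all, 18 of 38 lists fixed before the data were examined passed with camera's preset correlation, 13 up and 5 down. With an estimated correlation 0 passed, and 2 lists had an unadjusted camera p under 0.05. That version rests on the residuals of 3 arrays, which also set its degrees of freedom, so few lists could pass it. Its estimates were 0.0089 for glutathione S-transferases, -0.0014 for P450 genes and -0.0043 for ABC transporters, below the preset 0.01. The loss of these calls therefore does not show correlation between their genes. For ribosomal proteins the estimate was 0.25 and for histones 0.24. In limma's fry, which tests whether members move on balance in a direction and compares no list with other genes, 24 lists passed. The called lists of class III peroxidases, jasmonate, histones and ribosomal proteins did not (fry, Benjamini-Hochberg adjusted p = 0.0576, 0.0638, 0.195 and 0.188). Passing fry but not camera were the MATE, quinone reductase, thioredoxin, MYB, receptor-like kinase, abscisic acid, phenylpropanoid, nutrient transporter, chromatin modifier and seed lists. Only 9 of the 18 camera calls held under each of the 21 alternative settings, those of the glutathione S-transferases, antioxidant enzymes, class III peroxidases, heat shock proteins, heat stress transcription factors, WRKY factors, pathogenesis-related proteins, cell wall genes and cell cycle genes. Array weights and the alternative variance model entered the gene tests but not camera, so list calls could not change under those settings. On the slide of replicates 1 and 2, on the other slide and with slide as a term, the medians were 0.69, 0.46 and 0.56 for glutathione S-transferases and 0.77, 0.62 and 0.62 for heat stress transcription factors. For WRKY factors they were 0.67, 0.46 and 0.57, for heat shock proteins 0.18, 0.15 and 0.14, and for pathogenesis-related proteins 0.53, 0.20 and 0.31. Those of the antioxidant enzymes were 0.26, 0.21 and 0.26, of the class III peroxidases -0.16, -0.19 and -0.20, of the cell cycle genes -0.23, -0.14 and -0.18 and of the cell wall genes -0.19, -0.16 and -0.21. In the same order they were 0.18, 0.17 and 0.18 for P450 genes, 0.26, 0.05 and 0.15 for UDP-glycosyltransferases and 0.12, 0.17 and 0.15 for ABC transporters. AP2/ERF genes had 0.23, 0.21 and 0.34, NAC genes 0.21, 0.29 and 0.38, jasmonate genes 0.37, 0.39 and 0.35, gibberellin genes 0.59, 0.15 and 0.15, histones -0.05, -0.20 and -0.17 and ribosomal proteins -0.19, -0.06 and -0.12. Over the alternatives the median moved by more than 1.5 times for all called lists but the heat stress and WRKY factors. It ran from 0.51 to 0.97 for glutathione S-transferases, 0.17 to 0.43 for antioxidant enzymes, 0.25 to 0.71 for pathogenesis-related proteins, -0.37 to -0.03 for class III peroxidases, -0.35 to -0.06 for cell wall genes and -0.39 to -0.07 for cell cycle genes. For P450 genes it ran from 0.07 to 0.32, UDP-glycosyltransferases 0.06 to 0.32, ABC transporters -0.02 to 0.25, NAC genes 0.14 to 0.44, AP2/ERF genes 0.18 to 0.44, jasmonate genes 0.20 to 0.50, gibberellin genes 0.14 to 0.64, histones -0.26 to 0.11 and ribosomal proteins -0.26 to 0.08.

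The other 20 lists were not called (limma camera, Benjamini-Hochberg adjusted p from 0.0683 to 0.836). Rises and falls numbered 28 and 15 of 95 for MATE efflux proteins (31 and 19 adjusted over the list alone), 24 and 6 of 87 for thioredoxins, glutaredoxins and peroxiredoxins (24 and 5), 44 and 14 of 143 for MYB factors (45 and 17) and 32 and 13 of 87 for receptor-like kinases (34 and 15). They were 9 and 6 of 32 for the MAP kinase cascade (9 and 7), 26 and 26 of 110 for calcium signalling (29 and 28), 5 and 2 of 15 for ethylene synthesis (5 and 3), 27 and 7 of 77 for abscisic acid (28 and 7) and 25 and 13 of 88 for auxin response (26 and 13). Phenylpropanoid synthesis had 22 and 6 of 61 (24 and 8), terpenoid phytoalexin synthesis 3 and 2 of 16 (3 and 2), aquaporins 1 and 5 of 14 (1 and 5), nutrient transporters 12 and 8 of 36 (13 and 8), chromatin modifiers 7 and 0 of 25 (7 and 0), proteasome subunits 7 and 4 of 54 (5 and 2) and fermentation enzymes 11 and 7 of 53 (11 and 8). Quinone and carbonyl reductases, the enzymes closest to juglone's chemistry, had 5 rises and 1 fall among 19 members (5 and 1), with a mean of 0.16, a camera direction of down and a median of -0.01 that became 0.11 with median centring alone. Their largest rise was an aldo/keto reductase (Os04g0339400) with 3.94 ± 0.59 and their fall another (Os03g0237100) with -1.54 ± 0.42, both of a broad family whose substrates are not given by the description. Camera's direction is relative to the other genes, so down can go with a mean above 0. The MAP kinase cascade and calcium signalling too had a median below 0, a mean above 0 and camera's direction down. Their medians turned to 0.07 and 0.09 with median centring alone. For proteasome subunits median and mean were above 0 and camera's direction was down. Their median of 0.01 became -0.12 with the scanner software's log ratio. With median centring alone it was 0.22, and the list passed upwards with 21 rises and 1 fall. The phenylpropanoid list passed upwards without replicate 2 (median 0.16), with median centring alone (0.30), with the scanner software's log ratio (0.09), also when moved to the main medians (0.24), with the deposited value table (0.09) and with the mean of a gene's probes (0.15). Chromatin modifiers passed upwards with median centring alone (0.33), and without replicate 3 the aquaporins passed downwards (median -0.31), as they did with each probe on its own (-0.34), with the mean of a gene's probes (-0.35), with genes brighter than every random-sequence probe (-0.47) and with ribosomal centring (-0.12). The call of Os03g0237100 ended with unpaired channels. Off-name members led some lists, such as a heavy metal transport protein (Os04g0400800, -1.27 ± 0.27) in the MATE list, allyl alcohol dehydrogenases (Os11g0255500, 3.88 ± 0.70, and Os12g0226900, -1.50 ± 0.25) among fermentation enzymes, and 6'-deoxychalcone synthase (Os04g0447700, 4.62 ± 0.62), a flavonoid enzyme, in the phenylpropanoid list.

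The lists of markers of other tissues were not called by camera. Of 51 photosynthesis genes, kept as shoot markers, 9 rose and 3 fell (6 and 2 adjusted over the list alone), with a median of 0.07 that became -0.02 with the scanner software's log ratio and -0.07 with median centring alone. Chlorophyll a-b binding protein 1 (Os09g0346500) had log2 ratios of 3.06 and 2.90 in replicates 1 and 2 and 0.21 in replicate 3, and its call ended without replicate 1 (mean 1.56) or 2 (mean 1.64), with the scanner software's log ratio, as given or moved to the main medians, with the deposited value table, with ratios scaled between arrays, with no filter on dim probes and with the mean of a gene's probes. Of 21 seed storage and oil body proteins 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.17, and a glutelin family gene (Os12g0283400) rose by 2.86 ± 0.26. The seed list passed in limma's fry (Benjamini-Hochberg adjusted p = 0.0403) and, like the reference genes, in camera with each probe on its own (medians 0.48 and -0.28). Of 25 reference genes 3 rose and 7 fell (4 and 8 adjusted over the list alone), with a median of -0.14 that became 0.06 with median centring alone and -0.17 with the mean of a gene's probes, where the list passed downwards, a polyubiquitin gene (Os06g0681400) rising by 1.32 ± 0.24. With unpaired channels the call of Os09g0346500 ended too, as did those of Os06g0271000, Os08g0167000, Os06g0115400, Os05g0129800, Os03g0707600 and Os02g0438200 named above, while the phenylpropanoid list passed.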

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

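The tests of chance and of the centre of the ratios, the random-sequence check, the sort by water signal and the matched lists under median centring were chosen after the results were seen. The tests of base composition, second probes, mean intensity and matched lists with the main scaling were written before theirs. The test of second probes at first asked only for a different sequence, and was made stricter after that value was seen. Of 12 design-control probes with a random sequence, 6 were well above background on at least 2 arrays, which no comparison above uses. The brightest had a mean log2 intensity of 7.97, above that of 5224 tested genes, of which 968 were called changed. With genes brighter than that probe alone, 4800 rose and 3362 fell. Some named genes lay below 7.97 in the water channel, after Aquantile, such as Os11g0255500 (6.78), Os12g0283400 (7.03) and Os02g0546600 (7.60). A part of their water signal may be unspecific, so their folds are uncertain to that extent. The random-sequence probes had a median absolute log2 ratio of 0.04, but the brightest had 0.46 ± 0.40, so unspecific signal need not have a ratio of 0.

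With 3 arrays there are 4 assignments of sign, of which 1 (the real one) gave as many called genes, 9045 against 0 in the highest other. So few assignments cannot give a share under 0.05. Against a dye bias tied to a probe's bases, base composition explained 0.408% of the variance of the called genes' ratios. Against an artefact of the chosen probe, the second probe kept the direction in 95.063% of the 1195 called genes that had a second probe sharing no stretch of 15 bases with the first; called genes without such a probe were not covered. A dye bias of a gene unrelated to base composition cannot be told apart from juglone, since no array had the dyes swapped, and a response to juglone is the biological candidate explanation.

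The excess of rises among changes of at least 2-fold could come from water signals too low to show a fall, but among the brightest 6483 genes by mean intensity rises outnumbered falls 7.156 times (551 to 77). A rise itself lifts a gene's mean intensity, and sorting by water signal instead, which favours falls at the top since water is the ratio's denominator, left 341 rises and 123 falls in the top 6483 genes, so low water signal is not the whole source but may be a part of it. Where the ratios are centred stays open as a part of it, since under 3 other centres the lowest ratio of rises to falls was 2.152, with the scanner software's log ratio, between the values that would have spoken for or against it. That log ratio moved to the main medians gave 4.35 against 7.11, so it differed by more than its centre. A response made mostly of inductions stays open with these.

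The ribosomal protein list turned from -0.14 to 0.08 with median centring alone, so an intensity-dependent bias of abundant genes was a candidate explanation. Among 10000 random lists matched on intensity, 0% had a median at or below that of the ribosomal proteins. With median centring alone it was likewise 0% of 2000 lists, whose own median was 0.28. Relative to equally bright genes the list was thus lower under either scaling, while its absolute sign depends on the centre. The call, like that of every other list, did not hold with an estimated correlation, which was 0.25 for this list. A change shared by correlated genes on few arrays thus stays open beside a response to juglone.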

How the results depend on the processing

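Centring on the ribosomal list, the slide term, the random-probe filter and moving the scanner ratio to the main medians were chosen after seeing the data. No gene called with the main settings was called in the other direction under any of the 21 alternatives, except 1 with the mean of a gene's probes. Falls of at least 2-fold were 191 with median centring only, where the camera direction of the ribosomal (median 0.0773) and proteasome (median 0.2244, called up there) lists reversed, as did that of lists called in neither setting (quinone reductases, MAP kinases, calcium signalling, reference genes, terpenoid synthesis and photosynthesis). With the scanner software's log ratio 5939 genes fell, 1066 at least 2-fold, and with the series' deposited values 5943 fell, 1066 at least 2-fold. Moving the scanner ratio to the main medians left 606 falls of at least 2-fold. Ribosomal centring, a shift by construction, gave 2040 falls, 149 at least 2-fold. Scaling between arrays left 11 lists, and array weights gave 5421 falls. Apart from ribosomal centring, the cause was not tested. Without the replicate block (unpaired channels) 3866 genes changed, 2803 rose, 1063 fell and 187 fell at least 2-fold. Leaving out 1 replicate gave 3139 to 10595 changed genes, 2447 to 6261 rises, 692 to 4334 falls and 222 to 524 falls of at least 2-fold, with fewer arrays in each fit. The highest counts came without replicate 3, from the pair that shared a slide, and passed the 9045 changed genes of all 3 arrays. That pair also shared the scanner and software version, in which replicate 3 differed, so slide cannot be told apart from these. Whether sharing them narrows the spread between replicates was not tested. Of the 82 named genes 57 kept direction and call under all alternatives that tested them, and 25 lost the call under at least 1. Of the 18 list calls 9 held throughout, though array weights and the alternative variance model did not enter camera and could not change them. Signal over background leaves 183 rises and 4 falls with a bound in place of a fold.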

Other observations

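The tests of gene families were chosen after the data were seen; the test of neighbouring loci was written before its result, and pairs sharing probe sequence were left out only after its first value was seen. Outside the fixed lists, families sharing a description and at least 10 tested loci (139 families) were tested against the 25645 tested loci with Fisher's exact test and Benjamini-Hochberg adjustment, which treats genes as independent. U box domain proteins, many of which act as ubiquitin ligases, held 20 rises and 2 falls among 40 loci (adjusted p = 0.00326, Fisher's exact test), and this enrichment held under each of the 5 scalings tried. RING domain proteins, another ubiquitin ligase class, held 67 rises and 30 falls among 217 (adjusted p = 0.0266, Fisher's exact test), but 46 and 49 with the scanner software's log ratio, where the enrichment was lost and the median turned to -0.02, and the enrichment was also lost with ribosomal centring (median 0.25). AAA ATPases held 16 rises and 1 fall among 32 (adjusted p = 0.0124, Fisher's exact test), an enrichment lost with median centring alone and with ribosomal centring. Protein kinase domain genes held 129 rises and 85 falls among 447 (adjusted p = 0.00465, Fisher's exact test), also lost with median centring alone and ribosomal centring, and their median turned to -0.07 with the scanner software's log ratio.

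Other families were enriched for falls. Exostosin-like proteins, a glycosyltransferase family, held 11 falls and 0 rises among 19 loci (adjusted p = 0.00134, Fisher's exact test), an enrichment lost with median centring alone. Nonaspanin membrane proteins held 8 falls and 0 rises among 16 (adjusted p = 0.0253), sulfotransferases 8 and 0 among 17 (adjusted p = 0.0326) and family 8 glycosyl transferases 9 falls and 3 rises among 22 (adjusted p = 0.0485, Fisher's exact test for each). Each of these last 3 lost the enrichment under at least 1 scaling. Proteins described as prenyltransferase domain proteins held 4 rises among 125, fewer than the 21.1% of all loci that rose (adjusted p = 3.98e-06, Fisher's exact test), and this deficit held under each of the 5 scalings, as did that of TPR-like proteins (36 rises among 302, adjusted p = 0.00326, Fisher's exact test). Falls numbered 22 and 40 in these families, without enrichment. With the scanner software's log ratio they were 56 and 99, both enriched (adjusted p = 2.30e-05 and 0.00374, Fisher's exact test). With median centring alone the prenyltransferase falls were 32, also enriched (adjusted p = 0.0135, Fisher's exact test).

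Neighbouring loci may share a part of their response. The log2 ratios of adjacent loci correlated across genes, which are not independent, with a Pearson r of 0.0943 over 16555 pairs that had neither a description, a list nor a stretch of 15 probe bases in common, against at most 0.0230 in 1000 shuffles of locus order within chromosomes. The correlation was 0.0872, 0.0904 and 0.0958 on the 3 arrays and fell to 0.0071 at 4 steps. Both loci rose at least 2-fold in 171 pairs, against 96.1 from independent members. Adjacent loci lay a median of 12566 spot numbers apart on the array against 12269 for random loci, so they were not closer by this measure. A running spot number does not measure distance between rows, and a median can miss a small share of close pairs, so array layout is not excluded. Unrecognised relatives and transcripts split between 2 locus models stay open as sources, and neither was tested.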
